A study of Rattus norvegicus with 16 samples.

How the data were processed

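Total RNA from adult rat ventricular fibroblasts in culture was sequenced as stranded, polyA-selected bulk libraries, per the labels' protocols. The cells were grown in 20% serum and treated for 48 h in 0.1% serum with DMSO, TGFb, SW033291 or both agents, with 4 biological replicates per group. Group and replicate were taken from the labels of each sample. The labels give the same replicate numbers in all groups without saying that a number marks a shared animal or day.

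The authors deposited raw counts per gene for 32623 rat Ensembl gene IDs, 1 column per library, and replicates were not pooled. Per the submitters' processing notes, the tools were Trim Galore 0.6.4, STAR 2.7.5c, R 3.3.3 and DESeq2 1.14, and the genome build was Rnor_6.0. The counter, the annotation release, the strand setting and any filter are not given in the sources used here. Counts of genes that overlap, lie antisense to each other or share reads with near-identical copies are therefore uncertain. The values were whole numbers whose sums differed between libraries, and 0 rows named no gene. Totals ranged from 21037980 to 41340483, and 99.97% to 99.98% of the counts of each library lay in the genes tested.

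The main test was the quasi-likelihood test of edgeR 4.0.16 (glmQLFit and glmQLFTest) in R 4.3.3 on the deposited counts, with TMM composition factors and genes kept by filterByExpr over the 4 groups, which left 13753 genes. All 16 libraries were fitted as 4 group means with a shared estimate of the spread and no block. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the tested genes, with a threshold of 0.05. The contrasts were TGFb against DMSO, SW033291 against DMSO, the combination against TGFb, the combination against SW033291, the combination against DMSO, and the interaction, which is the inhibitor effect with TGFb minus that without. Standard errors of log2 fold changes were derived from the fold change and its F statistic. CPM values were scaled by the composition factors, and log2 CPM for principal components and scores used a prior count of 2. The common biological coefficient of variation was 4.82%.

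Genes moving back were those called in TGFb against DMSO and called in the opposite direction in the combination against TGFb. Chance levels came from the product of list sizes over the number of genes, from 20 simulations of unchanged groups, and from all 6 assignments of the 4 TGFb libraries into 2 and 2. The test was checked in 3 runs on simulated counts with the library sizes of these libraries. All 16 libraries were drawn from the DMSO means, so the TGFb means and the separate position of SW033291 replicate 4 were not reproduced. Known fold changes of 1.25, 1.5, 2 and 3 were set in the libraries with SW033291, in 150 genes per size over the 3 runs together. These genes were drawn from those averaging above 1 CPM. For SW033291 against DMSO the test called 72% of changes of the smallest size, 94% of 1.5-fold, 98% of 2-fold and 100% of 3-fold changes, with 32 calls among unchanged genes over the runs. For the combination against TGFb it called 75.3%, 94%, 100% and 100%, with 20 such calls.

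Libraries within a group were compared by a chi-square of their counts over genes with at least 20 counts in the pair. Alternatives fixed before the data were examined were the size factors of DESeq2 inside edgeR, total library size, no filter, a stricter filter (at least 1 CPM in at least 4 libraries and a mean of at least 50 counts), the Wald test of DESeq2 1.42.0, limma-voom (limma 3.58.1), the replicate number as a block, only the groups compared in the fit, and leaving out each library in turn. Limma-voom with library quality weights was added after the data were seen.

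The count table gives IDs without gene symbols, and 0 of the 32623 IDs were found in the reference gene table used here. Gene lists, markers of other cell types, the gene of the inhibited enzyme, and checks of GC content or gene length were therefore not analysed here. The rule for named genes, fixed before the data were examined, took genes past the threshold with a symbol, a mean of at least 5 CPM over the libraries compared and no overlap of the values of the groups, ranked by log2 fold change. With no symbols it was applied to IDs and reduced to 2 that rose and 2 that fell, the first in each direction in TGFb against DMSO and in SW033291 against DMSO.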

Results

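RNA sequencing counts were collected from cultured adult rat ventricular fibroblasts, the matrix-producing cells of the heart wall, after 48 h of treatment in medium with 0.1% serum. The 16 libraries formed a two-factor design with 4 biological replicates in each of 4 groups. The groups received vehicle (DMSO), transforming growth factor beta (TGFb, a cytokine that activates fibroblasts), SW033291 (a small-molecule inhibitor of 15-PGDH, the enzyme that degrades prostaglandins), or TGFb together with SW033291. The labels call the replicates biological without naming the animals they came from, and the p-values measure the spread between these cultures. Counts per library totalled 28938968 ± 5270473 in DMSO, 35418417 ± 6233084 in TGFb, 30782456 ± 879212 in SW033291 and 36492499 ± 5034455 in TGFb with SW033291 (SD, n = 4 each). The lowest total was 21037980 and the highest 41340483. Genes are given by their rat Ensembl IDs, because the sources used here do not pair these IDs with gene symbols, and 4 IDs are named.

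The libraries separated by TGFb treatment along the first principal component, which held 82.6% of the variance of log2 CPM (counts per gene scaled to library size). The 8 libraries without TGFb lay between -49.38 and -45.34 and the 8 libraries with TGFb between 45.85 and 49.43. The 20 most abundant genes held 14.67% ± 0.20 of the counts in DMSO, 14.62% ± 0.57 in SW033291, 18.1% ± 0.60 in TGFb and 17.97% ± 0.24 in the combination (SD, n = 4 each). One library, SW033291 replicate 4, stood apart from its group on the second component, which held 2.5% of the variance, with a score of 27.09 against -8.24 to 9.70 in the other 15. Its counts differed from those of the other 3 SW033291 libraries by a chi-square of 32.78 to 39.85 per degree of freedom, against 1.72 to 2.8 among those 3 and 1.72 to 10.03 over the 21 other pairs within groups. No pair of libraries within a group differed by as little as sampling noise, so no pair looked like 1 library sequenced again. That check cannot tell separate cultures from repeated preparations of 1 culture. Each library was counted as 1 replicate because the labels call the replicates biological.

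**Figure D1:**
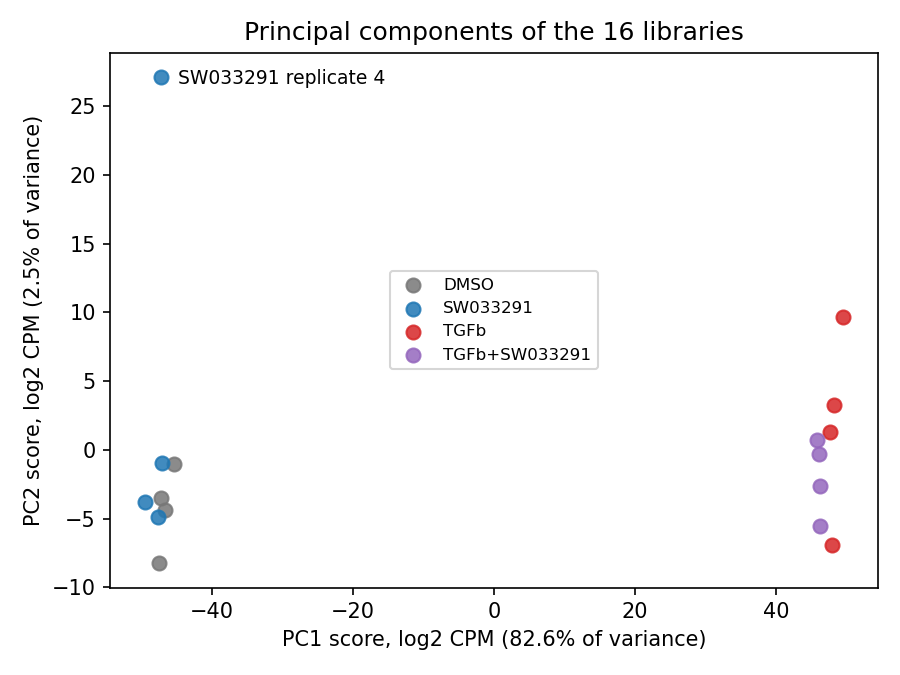
Principal component scores of the 16 libraries computed from log2 CPM, with the first component (82.6% of the variance) on the horizontal axis and the second (2.5%) on the vertical axis; each point is 1 library and the color gives its group. TGFb treatment separated the libraries along the first component, and SW033291 replicate 4 had a second-component score of 27.09.

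The first comparison asked how the fibroblasts responded to TGFb alone. Expression changed in 9073 of 13753 tested genes, or 66%, with 4498 higher and 4575 lower in TGFb than in DMSO. ENSRNOG00000043113 had the largest rise by the naming rule, from 0.0723 ± 0.042 CPM in DMSO to 12.7 ± 0.74 CPM in TGFb (SD, n = 4 each), a log2 fold change of 7.34 (SE 0.17, edgeR adjusted p = 7.2e-20). ENSRNOG00000009790 had the largest fall, from 16.4 ± 0.33 CPM to 0.112 ± 0.025 CPM (SD, n = 4 each), a log2 fold change of -7.17 (SE 0.16, edgeR adjusted p = 4e-20). Each of these rested on few counts in the lower group, 9 and 15 over 4 libraries. The ratios of the summed counts, each divided by the scaled library sizes of its group, were 170 (95% exact interval 89.4 to 373) and 149 (89.9 to 266). These intervals cover counting error only. They are already wider than the SEs of 0.17 and 0.16 imply, so those SEs are too small. Among the changed genes, 713 were at least 2-fold higher and 1030 at least 2-fold lower. Changes of at least 8-fold were found in 105 raised and 144 lowered genes. The median absolute log2 fold change of the called genes was 0.417. The split between higher and lower calls depended on the scaling. With total library size in place of composition factors, 3113 genes were higher and 6030 lower, as the median of all genes then lay at -0.117 on the log2 scale.

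The response to TGFb in the presence of SW033291 was measured by comparing the combination with SW033291 alone. Here 8829 genes changed, of which 4313 were higher and 4516 lower. ENSRNOG00000043113 stood at 0.0862 ± 0.055 CPM in SW033291 and 12.7 ± 0.14 CPM in the combination, and ENSRNOG00000009790 at 13.0 ± 1.6 CPM and 0.142 ± 0.048 CPM (SD, n = 4 each). The log2 fold changes of these genes were 7.15 (SE 0.16, edgeR adjusted p = 5.2e-20) and -6.48 (SE 0.15, edgeR adjusted p = 1.7e-19). These SEs are also too small, as the lower groups held 11 and 20 counts. The ratios of the summed counts, scaled as above, were 148 (95% exact interval 82.8 to 298) and 91.3 (59 to 150), from counting error only. This comparison shares no library with TGFb against DMSO. Both comparisons called 3731 genes higher and 3844 lower, against 1411 and 1502 for independent lists of these sizes, and 18 genes were called in opposite directions. The log2 fold changes of the 2 comparisons correlated across genes with a Pearson r of 0.956 and a Spearman rho of 0.909, genes not being independent replicates. In the combination against DMSO, 8980 genes changed, with 4430 higher and 4550 lower. With total library size as the scaling, the higher and lower calls became 2978 and 6056 for the first of these comparisons and 3087 and 5932 for the second.

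**Figure D2:**
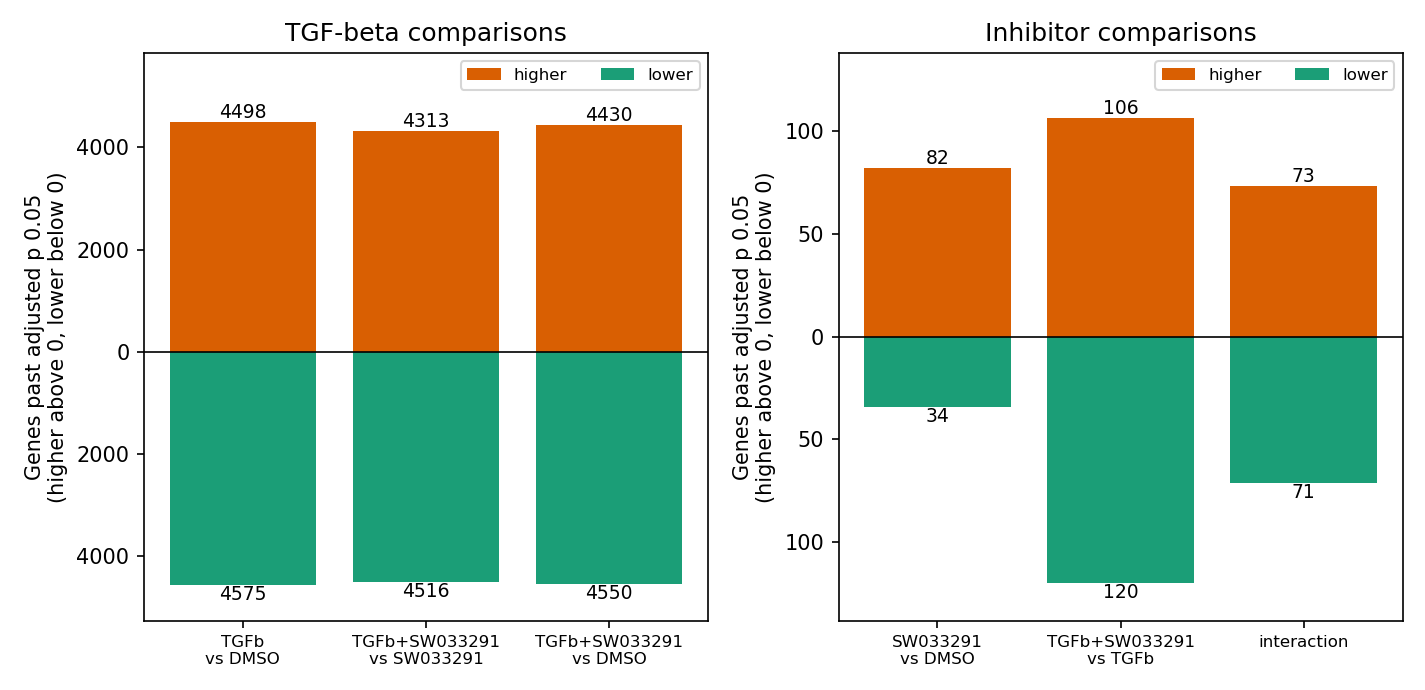
Number of genes past an adjusted p of 0.05 in each comparison (edgeR, 13753 genes tested, 4 libraries per group), with genes higher in the first-named group above 0 and genes lower in it below 0; the vertical scales of the panels differ. Comparisons of cells with and without TGFb called between 8829 and 9073 genes, and those of cells with and without SW033291 called 116 and 226, with 144 genes in the interaction.

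The effect of the inhibitor on cells without TGFb was much smaller in the number of genes. SW033291 against DMSO changed 116 genes, 82 higher and 34 lower, and 9 of them, all higher, by at least 2-fold. Of these, 2 had a fitted rise of at least 8-fold, and both lay below the 5 CPM mean of the naming rule and are unnamed. One had 19 counts over the DMSO libraries and 243 over the SW033291 libraries, a 12-fold rise (95% interval 7.51 to 20.3 from counting error alone, edgeR adjusted p = 1e-06). The other had 0 counts in DMSO and 12 in SW033291, at least 3.7-fold for a floor of 3 counts over the group (edgeR adjusted p = 0.049), so its fitted size is not supported by the counts. ENSRNOG00000008015 had the largest rise by the naming rule, from 7.53 ± 0.51 CPM to 21.1 ± 1.7 CPM (SD, n = 4 each), a log2 fold change of 1.49 (SE 0.07, edgeR adjusted p = 9e-12). ENSRNOG00000045884 had the largest fall, from 26.3 ± 0.89 CPM to 18.5 ± 0.76 CPM (SD, n = 4 each), a log2 fold change of -0.50 (SE 0.05, edgeR adjusted p = 6e-06). TGFb alone also moved both genes in these directions, to 16.8 ± 1.1 CPM and 17.9 ± 1.5 CPM (SD, n = 4 each), with log2 fold changes of 1.16 (SE 0.07, edgeR adjusted p = 3.3e-12) and -0.56 (SE 0.05, edgeR adjusted p = 7.9e-09). ENSRNOG00000009790, which TGFb lowered, was also lower with the inhibitor alone, by a log2 fold change of -0.34 (SE 0.07, edgeR adjusted p = 0.021). That call was lost with only the groups compared in the fit (edgeR adjusted p = 0.12) and without SW033291 replicate 3 (0.082) or any 1 of DMSO replicates 1 (0.07), 2 (0.063), 3 (0.073) and 4 (0.052). The median absolute log2 fold change of the called genes was 0.279. In simulated counts for this comparison, with 150 changed genes at each size over 3 runs, all averaging above 1 CPM, the test called 94% of 1.5-fold changes. SW033291 replicate 4 enters this comparison, and without it 274 genes were called, 200 higher and 74 lower, among them 113 of the 116. The count was 64, 66, 73 and 66 without DMSO replicates 1 to 4 in turn and 77 without SW033291 replicate 1, DESeq2 called 107 higher and 106 lower, and a fit of only the groups compared called 40 higher and 4 lower.

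Adding SW033291 to TGFb-treated cells was the comparison closest to the question of whether the inhibitor alters the fibroblast response. The combination differed from TGFb alone in 226 genes, 106 higher and 120 lower. ENSRNOG00000008015 rose again, from 16.8 ± 1.1 CPM to 27.5 ± 1.2 CPM (SD, n = 4 each; log2 fold change 0.71, SE 0.06, edgeR adjusted p = 5e-07). ENSRNOG00000045884 fell again, from 17.9 ± 1.5 CPM to 10.9 ± 0.26 CPM (SD, n = 4 each; log2 fold change -0.72, SE 0.06, edgeR adjusted p = 3.7e-07). The 2 genes with the largest responses to TGFb by the naming rule were not called here. Means were 12.7 CPM in both groups for ENSRNOG00000043113 (edgeR adjusted p = 1) and 0.112 and 0.142 CPM for ENSRNOG00000009790 (edgeR adjusted p = 0.84). The latter rested on 15 and 20 summed counts, with a log2 fold change of 0.35 (SE 0.45), too few to tell a modest change from none. The median absolute log2 fold change of the called genes was 0.272. In simulated counts for this comparison, drawn from DMSO means, the test called 94% of 1.5-fold changes in genes averaging above 1 CPM. Although SW033291 replicate 4 is in neither group, it enters the shared estimate of the spread, and without it 630 genes were called, including all 226. The count was 120 and 134 without TGFb replicates 1 and 3, 129, 128 and 141 without combination replicates 1, 2 and 3, and 419 with only the groups compared in the fit.

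**Figure D3:**
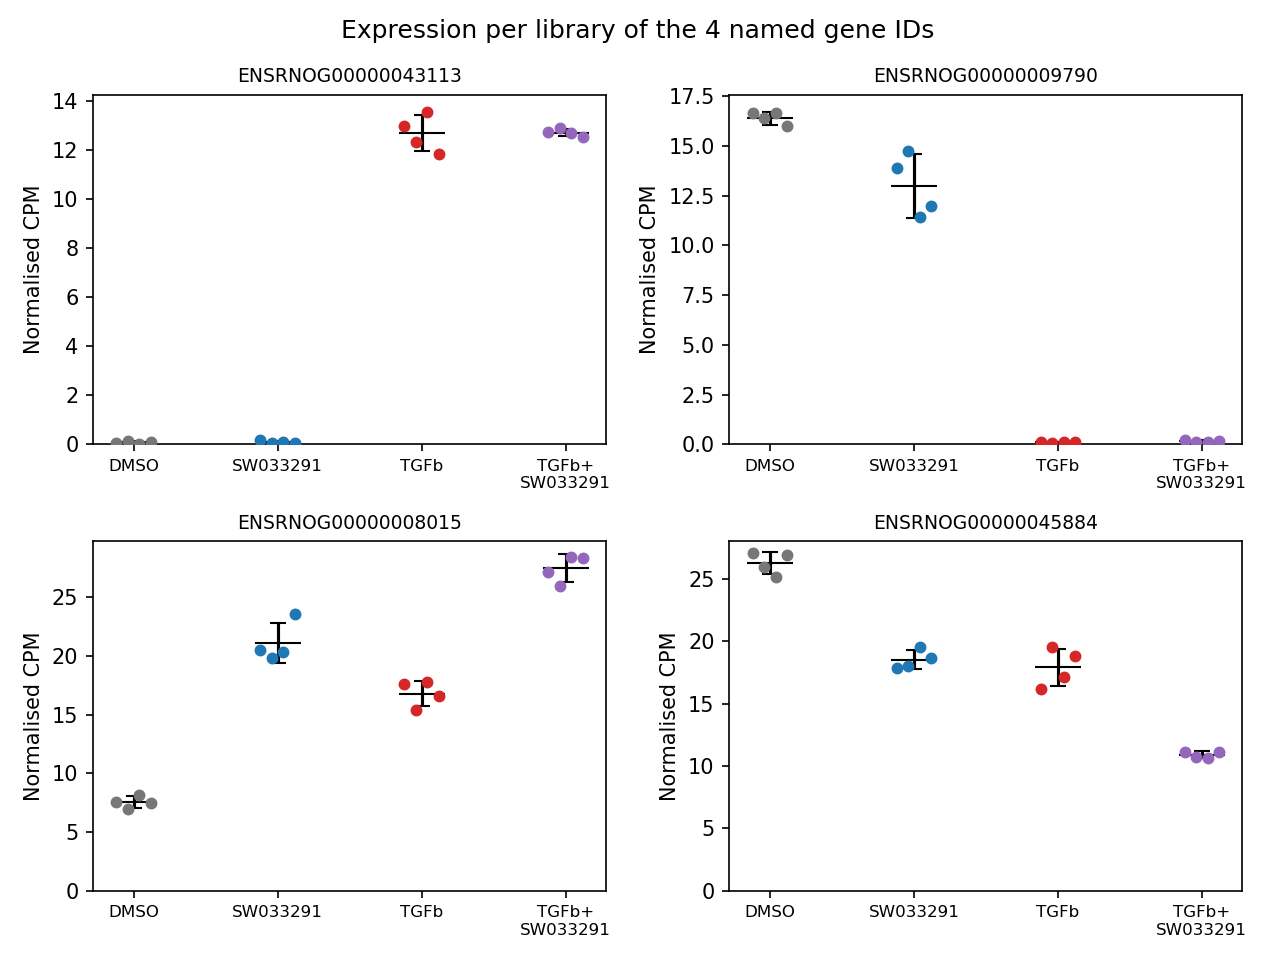
Normalised CPM of the 4 named gene IDs in each group; points are single libraries (n = 4 per group), horizontal bars are group means and error bars are SD. ENSRNOG00000043113 and ENSRNOG00000009790 followed TGFb treatment, while ENSRNOG00000008015 rose and ENSRNOG00000045884 fell with TGFb and with SW033291.

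The called genes of the 2 inhibitor comparisons overlapped, although the comparisons share no library. Both called 25 genes higher, against 0.63 for independent lists of these sizes, and 6 lower, against 0.30, and 2 genes were called in opposite directions, against 0.98. Of the 116 genes called without TGFb, 86 had the same sign with TGFb, and the median ratio of the fold change with TGFb to that without was 0.33 on the log2 scale, these genes having been chosen on the value without TGFb. Of the 226 genes called with TGFb, 105 (46.5%) had the same sign without it, and 327 of 630 (51.9%) when SW033291 replicate 4 was left out. Across all 13753 genes, most of them called in neither comparison, the log2 fold changes were nearly uncorrelated. The Pearson r was 0.029 (jackknife SE 0.027) and the Spearman rho -0.067. Over the 309 genes called in either comparison the Pearson r was 0.417, these genes having been chosen on the values correlated. Without SW033291 replicate 4, the overlaps were 55 genes higher, against 4.45, and 12 lower, against 1.72, with 14 opposite, against 6.3. Across all tested genes the Pearson r was then 0.048 and the Spearman rho 0.026, the latter with its sign changed. Over the 823 genes then called in either comparison the Pearson r was 0.261.

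The test of the interaction asked in which genes the inhibitor effect differed with and without TGFb. It called 144 genes, 73 with a positive and 71 with a negative difference. ENSRNOG00000008015 was among them, its rise with SW033291 being smaller in the presence of TGFb by a log2 difference of -0.78 (SE 0.09, edgeR adjusted p = 0.00018). The fall of ENSRNOG00000045884 did not differ past the threshold, with a log2 difference of -0.21 (SE 0.08, edgeR adjusted p = 0.25). The inhibitor effect had opposite signs in the 2 settings in 129 of the 144 genes, a number that choosing genes by the size of this difference itself raises, and for which no chance level was computed. TGFb alone raised 40 of the 144 genes and lowered 89, against 4498 and 4575 of all 13753 tested genes. The interaction is formed in part from the TGFb and DMSO libraries, so choosing genes on it can also add to these numbers. The inhibitor effect itself was past the threshold without TGFb in 31 of the 144 genes and with TGFb in 77, including 9 in both, while 45 passed in neither. The interaction count was 319 without SW033291 replicate 4, with 139 of the 144 among them, and 255 with DESeq2. It was 80, 79, 87 and 80 without DMSO replicates 1 to 4, 85 and 76 without TGFb replicates 1 and 3, 91 and 93 without SW033291 replicates 1 and 3, and 70, 77, 91 and 79 without combination replicates 1 to 4.

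The last comparison asked whether genes that responded to TGFb moved back toward the vehicle level when SW033291 was added. Of the 9073 TGFb-responsive genes, 77 were raised by TGFb and lowered by the addition of SW033291, and 75 were lowered by TGFb and raised by it, 152 in all. By contrast, 16 raised genes rose further and 35 lowered genes fell further. Independent lists of these sizes would give 39.2 and 35.3 genes moving back and 34.7 and 39.9 moving further. Because the TGFb libraries enter both comparisons with opposite sign, opposite changes arise without any effect. In 20 simulations of unchanged groups, 66.5% of genes had opposite signs and the fold changes had a correlation of -0.491 and a covariance of -0.0122. The observed data had opposite signs in 57.8% of all genes, a correlation of -0.215 and a covariance of -0.0366, which lay below the simulated covariance by a difference of -0.0244. With the TGFb libraries split so that each comparison had its own, the 6 assignments gave 39 to 111 genes moving back and 15 to 48 moving further, with covariances from -0.0332 to -0.0253.

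Of the 152 genes that moved back, 126 were still called against DMSO in the direction of the TGFb response, 25 were no longer called, and 1 was called in the opposite direction. The median absolute log2 fold change of the 152 genes was 0.84 in TGFb against DMSO and 0.27 in the combination against TGFb, and a median of 69.2% of the TGFb change remained. Choosing genes on comparisons that share the TGFb libraries biases these sizes, and with separate TGFb libraries the medians were 0.74 to 1.35 and 0.30 to 0.35 over the 6 assignments. Another 23 genes changed by the combination against TGFb had not been called in TGFb against DMSO. The number moving back was 407 without SW033291 replicate 4, 84 and 90 without TGFb replicates 1 and 3, and 90, 87 and 99 without combination replicates 1, 2 and 3. It was 280 with only the groups compared in each fit.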

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

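The tests of depth, of admixed RNA, of a missing inhibitor and of a state shared with other groups were chosen after the position of SW033291 replicate 4 was seen. In 36 sets of 4 library values, 4 held a library far from the other 3, where the distance used would pick out about 5% of such sets by chance. One was the total of DMSO replicate 1, 21037980 counts against 31315749 to 31717376, with a gap of 0.96 of the whole range. The inhibitor effect on ENSRNOG00000008015 differed with and without TGFb by a log2 difference of -0.78 (edgeR interaction test, adjusted p = 0.00018), and it was -0.72 without SW033291 replicate 4.

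The other 3 were all in SW033291 replicate 4. Its second principal component was 27.09 against -4.84 to -0.97 in its group, a gap of 0.88 of the range. Its 20 most abundant genes held 13.77% of the counts against 14.89% to 14.92%, a gap of 0.97, and the most abundant gene of the series held 1.1% against 1.78% to 1.82%, a gap of 0.94. RNA of TGFb-treated cells mixed into the library is argued against by the 105 genes that TGFb raised at least 8-fold. Their median in this library was -0.2 log2 (bootstrap SE over genes 0.084) relative to the other 3 libraries, where an admixture needs a rise. Depth is argued against because, with all 4 libraries of the group thinned to 21037980 counts, its chi-square against the others was still at least 23.21 per degree of freedom, against at most 2.28 among those 3, and its total of 32080137 was the highest of its group. A library that had no inhibitor is argued against by genes called in 4 fits without it and without 1 DMSO library each, in which it showed a median share of 0.6 to 0.75 of the shift of the other 3, while the DMSO library left out, measured on the same genes and baseline, showed 0.1 to 0.17. By direction alone the 2 libraries lay closer. With DMSO replicate 1 left out, 174 of 230 genes in SW033291 replicate 4 and 157 in that DMSO library went in the inhibitor direction. The numbers were 176 and 131 of 217 with DMSO replicate 2, 160 and 131 of 195 with replicate 3, and 159 and 128 of 199 with replicate 4. Whether it shares a state with libraries of other groups, as handling or RNA quality could produce, cannot be told apart from a culture of its own, because its deviation correlated with the leading axis of deviations in the other groups at 0.18 in size across genes, while the highest of the other libraries had 0.23. No biological explanation was tested, and GC content, gene length and markers of other cell types were not analysed here.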

How the results depend on the processing

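The counts for TGFb against DMSO (8066 to 9700), the combination against SW033291 (7833 to 9570) and the combination against DMSO (7926 to 9744) stayed within 1.5 times under every alternative run. The inhibitor counts did not. DESeq2 called 213 genes for SW033291 against DMSO and 255 for the interaction. With only the groups compared in the fit, SW033291 against DMSO gave 44 (40 higher, 4 lower), the combination against TGFb 419 and genes moving back 280. There the spread comes from those groups alone, and SW033291 replicate 4 enters the first only. Limma-voom with library quality weights, chosen after seeing the data, gave 463 for SW033291 against DMSO, 591 for the combination against TGFb, 442 for the interaction and 399 moving back. Leaving out 1 library gave 64 to 274 for SW033291 against DMSO, 120 to 630 for the combination against TGFb, 70 to 319 for the interaction and 84 to 407 moving back, the highest each time without SW033291 replicate 4, whose removal lowered the common coefficient of variation from 4.82% to 3.08%. Separate TGFb libraries for the 2 comparisons gave 55, 48, 39, 51, 111 and 52 moving back, with fewer libraries per comparison. Where no construction is named, the cause was not tested.

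The replicate number as a block gave 9065, 98, 211, 121, 8827 and 8979 calls for TGFb, SW033291, the addition of SW033291 to TGFb, the interaction, TGFb with SW033291 present and the combination against DMSO, and 147 moving back. The numbers did not clearly pair the libraries. The deviations of 24 same-number pairs correlated at -0.09 to 0.16, 2 above 0.1, against -0.23 to 0.12 for different numbers. Of 16 libraries, 4 correlated best with their own number. No test was run on this, so a weak pairing is not excluded. The correlation of the inhibitor effects across genes, called or not, stayed between 0.008 and 0.048. Of 273 recomputed fold changes of the named IDs, 267 kept direction and side of the threshold, 6 kept direction only, all of ENSRNOG00000009790 in SW033291 against DMSO, and 0 reversed. Gene list alternatives were not run, as the IDs were not paired with symbols. At this depth 94% of 1.5-fold changes were called in simulated counts for each of SW033291 against DMSO and the combination against TGFb. This holds for genes averaging above 1 CPM and drawn from DMSO means, not for all genes tested.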

Other observations

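The tests of the TGFb response score, of its dependence on TGFb and of scaling were chosen after the results they bear on were seen. The separate TGFb libraries and the counts over other groupings were planned, but the values that would decide them were written down after they were seen. Averaged over cells with and without TGFb, SW033291 changed 147 of 13753 genes, 86 higher and 61 lower, 6 by at least 2-fold. Compared with the TGFb effect averaged over both inhibitor states, which raised 5039 and lowered 5169 genes, the genes higher with the inhibitor included 47 that TGFb lowered, against 32.3 for independent lists, and 25 that it raised, against 31.5. The genes lower with the inhibitor included 31 that TGFb raised, against 22.3, and 29 that it lowered, against 22.9. Without SW033291 replicate 4, 493 genes changed, 317 higher and 176 lower, 11 by at least 2-fold. The genes higher with the inhibitor then included 196 that TGFb lowered, against 122.7, and 84 that it raised, against 120.7. The lower ones included 89 that TGFb raised, against 67, and 73 that it lowered, against 68.1. The averaged effects of TGFb and of the inhibitor are formed from the same libraries, so the values for independent lists need not be those expected without an effect, and no test was run on these overlaps.

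A hypothesis is that SW033291 lowers the genes that TGFb raises. A score was formed per library as the mean log2 CPM of 661 genes that TGFb raised at least 2-fold minus that of 1055 genes it lowered at least 2-fold, both chosen on the TGFb effect averaged over the inhibitor states. It was 1.964 ± 0.023 in TGFb and 1.86 ± 0.008 in the combination (SD, n = 4 each), a difference of -0.104 (SE 0.012), or -2.8% of the span between DMSO and TGFb, with the combination lower in 4 of 4 libraries. The exact two-sided permutation p was 0.029, the smallest this design allows, and 0.087 after Benjamini-Hochberg adjustment over 6 tests, which misses 0.05. Without SW033291 replicate 4, which is in neither group, the score genes were chosen again (698 raised and 1078 lowered). That exact permutation p then stayed at 0.029 and its adjusted value was 0.044, as tests of SW033291 against DMSO in the same family reached 0.029. The raised genes alone fell by 0.113 (SE 0.008, exact permutation p = 0.029, adjusted 0.087), and the lowered genes changed by -0.009 (SE 0.017, exact permutation p = 0.66). A scaling difference equal for all genes is argued against by the median change of the raised minus the lowered genes, -0.09 log2. Its bootstrap SE of 0.012 resamples genes and holds no spread between libraries. The median over all genes was -0.003, a value that composition scaling itself keeps small. A bias that depends on abundance was not tested.

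In cells without TGFb the score changed by -0.055 with the inhibitor (SE 0.026, exact permutation p = 0.11, adjusted 0.16). It changed by -0.061 (SE 0.032, exact permutation p = 0.029, adjusted 0.044) when SW033291 replicate 4 was left out. Leaving it out also renewed the choice of score genes, to 698 raised and 1078 lowered. On the genes chosen from all 16 libraries, SW033291 replicate 3 scored -1.783, above DMSO replicates 1 (-1.786), 3 (-1.791) and 4 (-1.787). The lower p-value thus cannot be put down to replicate 4 alone. In these cells without TGFb the raised genes changed by -0.021 (SE 0.023, exact permutation p = 0.43). The lowered genes changed by 0.034 (SE 0.017, exact permutation p = 0.086, and 0.046 with exact permutation p = 0.029 without replicate 4). For the whole score, the change with TGFb minus that without was -0.049 (SE 0.029), which does not separate them. For such differences within gene sets, the permutations exchanged the inhibitor label within each TGFb state. Their p-values are therefore exact only for no inhibitor effect in either state, not for equal effects in both. For the raised genes it was -0.092 (SE 0.024, exact permutation p = 0.054, adjusted 0.072 over 4 tests), and -0.106 (SE 0.021, exact permutation p = 0.023, adjusted 0.031) without replicate 4. With the 351 raised genes of at least 1 CPM in cells without TGFb it was -0.069 (SE 0.020, exact permutation p = 0.047, adjusted 0.072). For the lowered genes it was -0.043 (SE 0.024, exact permutation p = 0.099), -0.046 (SE 0.020, exact permutation p = 0.032, adjusted 0.072) for the 561 of at least 1 CPM in cells with TGFb, and -0.057 (SE 0.023, exact permutation p = 0.031, adjusted 0.031) for all lowered genes without replicate 4. The inhibitor may thus lower TGFb-raised genes more when TGFb is present, by 0.092. However, the permutation test over all 16 libraries misses 0.05 after adjustment and does not test equal effects directly. The lowered genes shifted in the same direction, so the shift is not shown to be particular to the raised genes. Differences in culture between the groups stay open.

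That genes moved back toward vehicle could come from the TGFb libraries that both comparisons share. With separate TGFb libraries for each comparison the covariance of the fold changes over all genes was below 0 in all 6 assignments, with -0.0253 nearest to 0. Sharing thus did not account for the whole of this covariance. The assignments reuse the same libraries and are not independent, and no spread between libraries was computed for it. The covariance covers all tested genes, not only those called as moving back. A difference between the cultures of the TGFb group and those of the other groups would remain in each assignment and was not tested.

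Calls were also counted for other groupings of the same libraries, and the real grouping gave the most of those counted each time. Other groupings mix libraries of both groups, so a real difference enters the spread and lowers their calls. For the comparisons of cells with and without TGFb, few calls elsewhere followed from the size of the response, and no conclusion is drawn. For the inhibitor comparisons, 1 of 35 is the smallest share the design allows. For TGFb against DMSO, 1 of 35 splits gave as many calls, the real one with 9073, and the highest other gave 0. For SW033291 against DMSO it was 1 of 35, with 116 and 0. For the combination against TGFb it was 1 of 35, with 226 and 1. For the interaction it was 1 of 100 drawn splits within each TGFb state, with 144 and 27, the latter from exchanging SW033291 replicate 4 with DMSO replicate 2. These draws kept DMSO replicate 1 and TGFb replicate 1 in their own groups. A grouping that exchanges all inhibitor labels in only 1 TGFb state was therefore never drawn. It would count the inhibitor effect averaged over both TGFb states, which called 147 genes, so no conclusion is drawn for the interaction. For the combination against SW033291 it was 1 of 35, with 8829 and 411, the latter from exchanging SW033291 replicate 4 with combination replicate 4. For the combination against DMSO it was 1 of 35, with 8980 and 0.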
